A study of Mus musculus with 2 samples.

How the data were processed

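Single-cell RNA libraries were made from tumours of mice given control IgG or an antibody against SIGLEC15, with 1 library per group. The design text gives 3 mice per group, and per the labels' protocols CD45 bead-enriched cells and unsorted cells were loaded at equal parts. Reads were counted with Cell Ranger 2.1.1, per the submitters' processing notes. The genome build, the cell filters and the clustering method are not given in the sources used here. For each library the authors deposited a list of cells, each with the name of 1 of 30 clusters, and a matrix of expression values. The deposited values are the natural log of 1 plus 10000 times the UMI count over the cell's total, which was tested on the values themselves.

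The antibody matrix held 18685 genes in 5482 cells. The copy of the IgG matrix used here held 105 complete genes in 5765 cells and stopped inside the next gene, so the other genes of that library were not analysed here. UMI counts were recovered from the logged values with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. In the antibody library every value above 0 was a whole number of UMIs within a tolerance of 0.001, and the sum over genes equalled the recovered depth in 5482 cells. When that depth was recovered from the 105 shared genes alone, it equalled the true depth in 5440 cells, differed in 8 and gave no value in 34. The same step gave a depth for 5739 IgG cells, and the other 26 had no UMI in the shared genes. Cells without a depth from the shared genes were left out of expression ratios in both libraries and kept in the shares of cells.

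The cell filter, the gene lists, the cell type markers, the rule for naming genes and part of the alternatives were fixed before the data were examined. The filter asked for at least 500 UMIs and 200 genes and at most 20% mitochondrial UMIs. It removed 0 antibody cells. For IgG cells only the UMI part was available. No IgG cell could fail it, because the recovery accepted only depths of at least 500 UMIs. The check on antibody cells cannot show an error from this, since their lowest depth was 553 UMIs. Classes were taken from the authors' cluster names. A class name was doubted where the 10 most specific genes of a cluster held more fixed markers of another type than of its own, which led to separate values for MDSC_1 to MDSC_4 and for T cells without the cluster named CD3_T. The cluster named DC held 2 monocyte markers and 1 dendritic cell marker and is reported under its deposited name.

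Shares of cells were given with exact Clopper-Pearson 95% intervals. Expression was the sum of a gene's UMIs over the cells of a class, scaled to CPM of the class total, and the ratio of the antibody to the IgG library had an exact conditional 95% interval. Classes with at least 50 cells in each library were compared. The named genes were up to 10 in each direction with the interval bound farthest from 1, among genes with at least 50 UMIs and at least 50 CPM in 1 library. Ribosomal, mitochondrial, haemoglobin and receptor genes and unnamed gene models were left out. Clusters were matched between libraries by the correlation of log2 CPM, with 20 added, over 77 shared genes. No p-value was computed, since cells of 1 library are not replicates. Gene positions came from GENCODE release M21 by symbol, and 102 of the 105 shared genes had one.

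The 20 fixed gene lists could not be compared between libraries, because only Mcm3 was shared. They were described in the antibody library alone, as the median log2 ratio of a class to all other cells over list genes with at least 10 UMIs. Its percentile came from 10000 random lists of the same size, matched on mean expression in 20 bins. The log2 ratios had a prior count of 0.5. Shares of cells with a UMI were given after each cell was thinned to 1000 UMIs, and cells with fewer were left out, among them 302 of 744 antibody MDSC. Thinned shares are expected values: each cell's chance of keeping a UMI was summed, and intervals used that sum rounded to whole cells. Doublets were predicted in the antibody library with scrublet in scanpy 1.11.5, and plots were drawn with matplotlib 3.10.9.

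The steps were run on simulated data, with class sums drawn as Poisson counts, the model that the interval assumes. Coverage near 95% thus follows from the setting, and spread between cells or mice was not simulated. In tumour cells, intervals of the ratio held the true value in 95.6% of draws for 56 unchanged genes and in 95.3% for 9 genes raised 1.5-fold. For the DC cluster the 1.5-fold figure was 94.0% over 3 genes. Of 20 simulated lists raised 1.5-fold in MDSC, among 15331 genes, 90.0% passed the 97.5th percentile, and 10.0% of unchanged lists did so in macrophages.

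Alternatives were a minimum of 1000 or 2000 UMIs, other scalings, a mean over cells, other thinning depths, other UMI minimums for lists, clusters weighted alike, and leaving out clusters. The clusters left out of the shares, MDSC_5, Unknown, Adipocyte, Tumor_4 and Macrophage_4, were chosen after seeing the data and not by the rule for doubted names. Siglec15 had no entry among the antibody library's genes and was not analysed here, nor were Calcr, Ms4a2, Mx1, Oscar and St6galnac1.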

Results

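Transcripts of single cells were counted in subcutaneous tumours of Hep1-6, a mouse hepatoma line, grown in C57BL/6 male mice. The mice received control IgG or an antibody against SIGLEC15, a receptor of the sialic acid-binding family studied as an immune checkpoint. There was 1 library per group, so no difference has a replicate check, and all intervals are 95% intervals that cover counting error only. The IgG library held 5765 cells and 85804877 UMIs, with a median of 15733 per cell with a known depth. The antibody library held 5482 cells and 74168827 UMIs, with a median of 13714.5 per cell. Between libraries, the cell annotation was compared in full and expression was compared for 105 genes. Siglec15 itself was not analysed here, so which cells expressed the target is not known. The treatment labels were not checked against expression.

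The first comparison asked how the make-up of the tumours differed between the antibody and IgG. Myeloid-derived suppressor cells (MDSC), T cells, macrophages and the cluster named DC all took larger shares of the antibody library, and tumour cells took a smaller one. MDSC_1 to MDSC_4 are neutrophil-like cells, with S100a8, S100a9, Csf3r and Il1b among their most specific genes, while MDSC_5 held macrophage genes. The T cells held CD4 and CD8 clusters and a cluster named CD3_T. The 10 most specific genes of CD3_T held Gzma, a marker of natural killer cells, Ly6c2, a marker of monocytes, and 0 T cell markers. As a whole, CD3_T scored highest for natural killer cell markers, with a mean log2 fold of 3.45. Called cell by cell, 56 of the 520 antibody T cells of all clusters went to natural killer cells. That call was not split by cluster, so how much of CD3_T they are is open. The most specific genes of the DC cluster held 2 monocyte markers and 1 dendritic cell marker. Because bead-enriched and unsorted cells were mixed in fixed parts before loading, that mixing can set the immune share.

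Immune cells made up 19.8% of the IgG library (1141 of 5765 cells, interval 18.8 to 20.8%) and 36.9% of the antibody library (2022 of 5482, 35.6 to 38.2%). The ratio was 1.86 (1.73 to 2.01). Tumour cells went from 75.7% to 58.6%, a ratio of 0.774 (0.740 to 0.811). MDSC_1 to MDSC_4 together went from 5.19% to 12.9% of all cells, a ratio of 2.49 (2.17 to 2.86). T cells without CD3_T rose from 3.82% to 6.97%, a ratio of 1.83 (1.54 to 2.17). Macrophages rose from 6.52% to 9.70% (ratio 1.49, 1.30 to 1.70) and the DC cluster from 2.46% to 3.79% (ratio 1.54, 1.24 to 1.92). Fibroblasts and endothelial cells had a ratio of 1.56 (1.21 to 2.03). B cells were few, with 20 and 18 cells, and no difference was detectable at this depth.

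**Figure D1:**
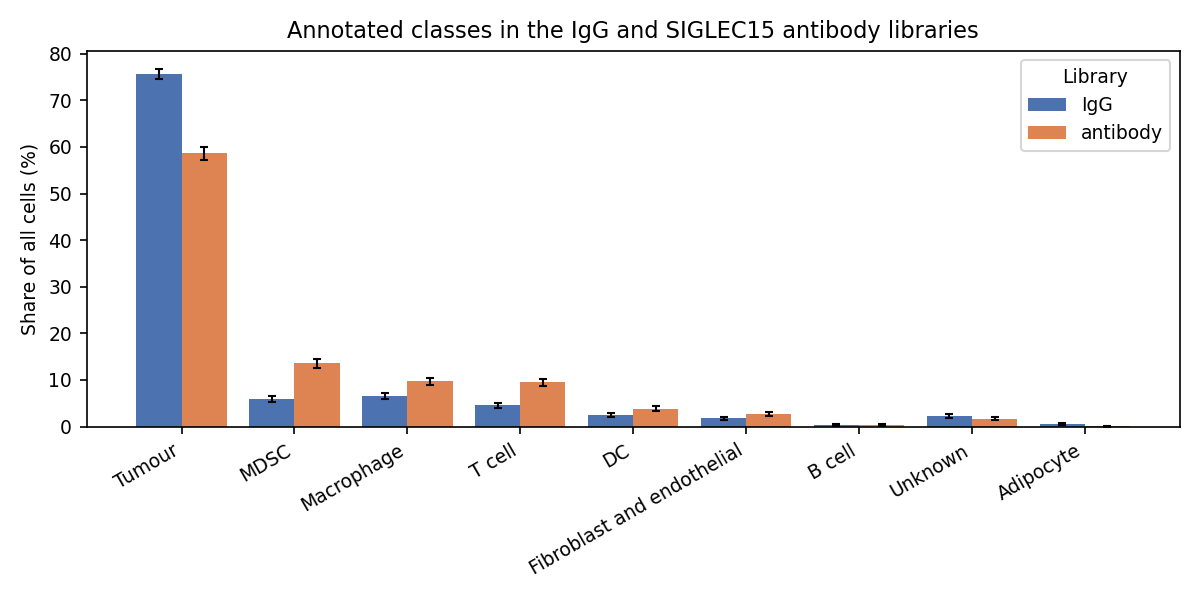
Share of all cells (percent) in each annotated class of the IgG and antibody libraries, with exact 95% intervals. Tumour cells took 75.7% of the IgG library and 58.6% of the antibody library.

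Among immune cells alone, neutrophil-like MDSC gained on macrophages. The gain was uneven: MDSC_3, whose cells in the antibody library carried the interferon-induced genes Isg15 and Rsad2, rose most. Macrophage_3, the cluster richest in Retnla, Mrc1 and Arg1 in that library, genes of alternatively activated macrophages, fell most relative to other immune cells, while Macrophage_1 and Macrophage_2 did not fall. MDSC_1 to MDSC_4 went from 26.2% to 35.0% of immune cells, a ratio of 1.33 (1.16 to 1.53). Macrophages went from 33.0% to 26.3%, a ratio of 0.798 (0.698 to 0.914), and with at least 2000 UMIs the interval of 0.768 to 1.04 includes 1. For T cells without CD3_T the ratio was 0.980 (0.828 to 1.16) and for the DC cluster 0.827 (0.665 to 1.03), and both intervals include 1.

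MDSC_3 rose from 40 to 180 cells, or from 3.51% to 8.90% of immune cells, a ratio of 2.54 (1.79 to 3.67). MDSC_1 had a ratio of 1.37 (1.08 to 1.74). CD3_T rose from 44 to 138 cells, a ratio of 1.77 (1.25 to 2.54). Macrophage_3 went from 104 to 91 cells, or from 9.11% to 4.50% of immune cells, a ratio of 0.494 (0.369 to 0.661). Over all cells its ratio was 0.920 (0.687 to 1.23), so its own share is not shown to change while other immune cells rose. Macrophage_1 had a ratio of 1.04 (0.804 to 1.34) and Macrophage_2 one of 1.00 (0.768 to 1.31). Macrophage_4 had a ratio of 0.689 (0.513 to 0.927) and CD8_T_2 one of 0.747 (0.568 to 0.984). With at least 1000 UMIs their intervals, 0.525 to 1.21 and 0.585 to 1.01, include 1. For CD8_T_2 the interval excludes 1 with at least 2000 UMIs (0.515 to 0.969). It also does so without MDSC_5, Unknown, Adipocyte, Tumor_4 and Macrophage_4 (0.544 to 0.941). Across 77 shared genes, which are not independent, the profiles of 23 of 30 IgG clusters correlated best with the antibody cluster of the same name. IgG Macrophage_4 was closer to Macrophage_1 (0.905) than to its own name (0.869, rank 8), and CD8_T_2 was closest to CD8_T_1. IgG MDSC_2 was closer to MDSC_3 (0.905) than to its own name (0.882), and IgG MDSC_4 closer to MDSC_1 (0.859) than to its own (0.842). It is open whether these names, and with them the rises of MDSC_3 and MDSC_1, mark the same cells in both libraries. IgG MDSC_3 (0.913) and MDSC_1 (0.876) were themselves closest to their own names. Only 6, 5, 5 and 2 shared genes reached 50 UMIs in MDSC_1, MDSC_2, MDSC_3 and MDSC_4, so small gaps between these correlations say little. CD8_T_1, a cycling cluster, had a ratio of 1.20 (0.938 to 1.54), and with at least 2000 UMIs one of 1.35 (1.04 to 1.75). Median depths of MDSC_3 were 999 UMIs in the IgG library and 1059 in the antibody library.

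**Figure D2:**
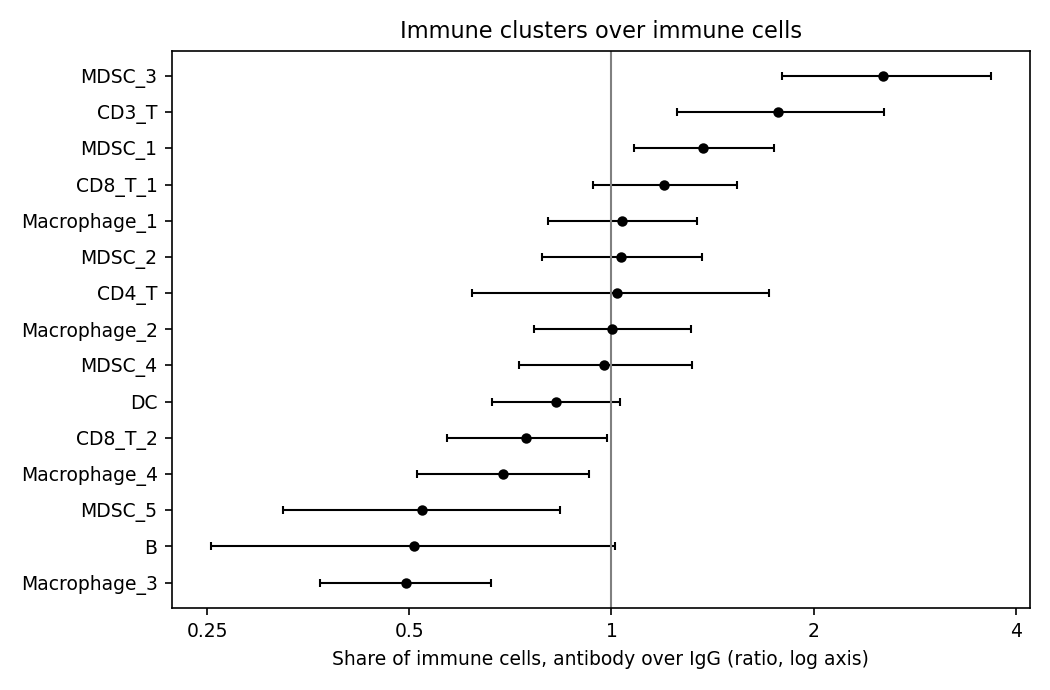
Ratio of each immune cluster's share of immune cells, antibody over IgG, on a log axis with 95% intervals. MDSC_3 lies highest at 2.54 and Macrophage_3 lowest at 0.494.

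Tumour clusters shifted among themselves as well. Tumor_4 went from 13.5% to 8.90% of tumour cells, a ratio of 0.657 (0.569 to 0.758). Its cells were shallow, with median depths of 2061 and 2483 UMIs, and its most specific genes mixed the mitotic gene Ube2c with Lars2, Gm42418 and AY036118. Tumor_2, with the mitotic genes Cenpf, Ube2c and Cdc20, had a ratio of 1.14 (1.01 to 1.29). Its interval includes 1 with at least 2000 UMIs (0.988 to 1.26) and when Tumor_4 is left out (0.961 to 1.22). Tumor_1, rich in the hypoxia genes Vegfa, Bnip3 and Ndrg1, had a ratio of 0.831 (0.738 to 0.934). Tumor_9, with the interferon-induced genes Cxcl10, Gbp2 and Iigp1, had a ratio of 1.36 (1.14 to 1.63). Tumor_6, rich in Alb and Apoa1, had one of 1.35 (1.16 to 1.58). Over all cells the ratios were 1.06 (0.882 to 1.26) for Tumor_9, 1.05 (0.897 to 1.23) for Tumor_6 and 0.885 (0.784 to 0.999) for Tumor_2. These clusters thus rose relative to other tumour cells, and a larger share of all cells is not shown.

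The second comparison asked which of the shared genes differed in expression within a class. In tumour cells Uggt1, which checks the folding of glycoproteins, and Tram1, which helps proteins enter the endoplasmic reticulum, were higher in the antibody library. Dst, a cytoskeletal linker, Cox5b, a subunit of the respiratory chain, and Rb1cc1, needed for autophagy, were higher too. Snhg6, a long noncoding RNA, Gsta3, a glutathione transferase, and Mrpl15, of the mitochondrial ribosome, were lower. All 102 shared genes with a known position lie on chromosome 1, because the copy of the IgG matrix held only its first genes, so the location says nothing of the differences. Positions are given on GRCm38.

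Uggt1 (ENSMUSG00000037470, 36140027 to 36244720) had a ratio of 1.32 (1.26 to 1.39) in tumour cells and lay above 1 in 11 of 11 tumour clusters. Tram1 (ENSMUSG00000025935, 13564698 to 13589910) had a ratio of 1.23 (1.19 to 1.27) and was also above 1 in 11 clusters. Dst had a ratio of 1.19 (1.17 to 1.22), Cox5b one of 1.14 (1.13 to 1.16), Rb1cc1 one of 1.16 (1.11 to 1.21) and Arfgef1 one of 1.09 (1.05 to 1.14). Gsta3 (ENSMUSG00000025934, 21240589 to 21265661) had a ratio of 0.825 (0.806 to 0.845) and lay below 1 in 11 of 11 clusters. Snhg6 had a ratio of 0.800 (0.780 to 0.821) and Mrpl15 one of 0.914 (0.886 to 0.943), each below 1 in 10 clusters. The cluster's interval excluded 1 in that direction in 8 clusters for Uggt1, 7 for Tram1, 9 for Gsta3, 4 for Snhg6 and 7 for Mrpl15. All clusters come from the same libraries, so they are not replicates. Tcea1 and Smap1 had ratios of 1.05 and 1.04, and both fell just under 1, to 0.999 and 0.994, when the median ratio was set to 1. The median log2 ratio of shared genes was 0.07 in tumour cells and 0.15 in all cells.

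**Figure D3:**
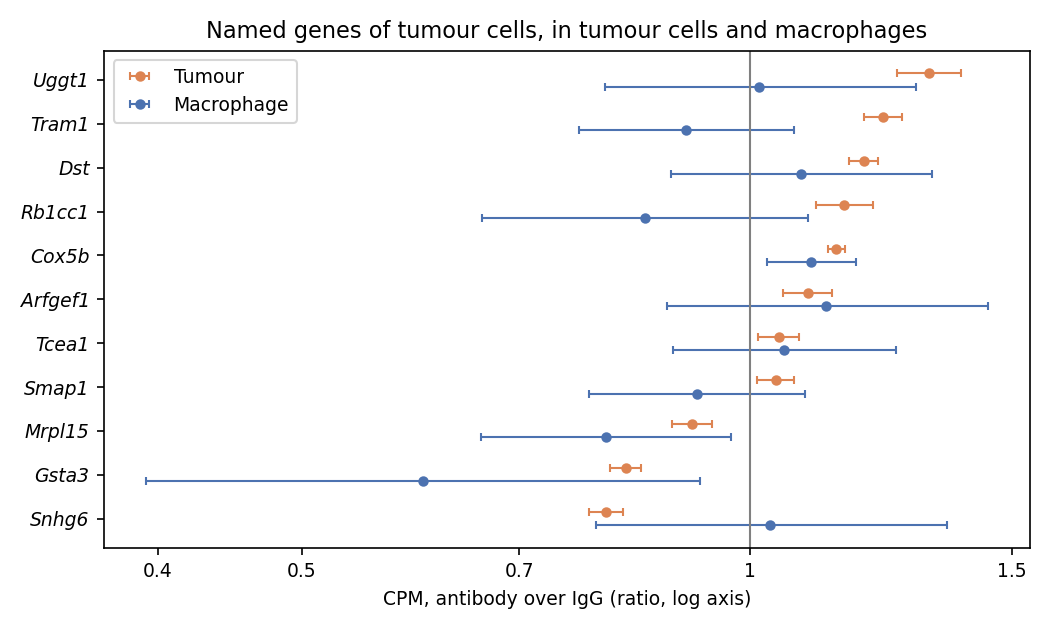
Ratio of CPM, antibody over IgG, on a log axis with 95% intervals for the named genes of tumour cells, shown in tumour cells and in macrophages. Uggt1 lies at 1.32 in tumour cells and at 1.01 in macrophages, a difference whose interval, adjusted for 11 genes, includes 0. Gsta3 lies at 0.825 in tumour cells and at 0.603 in macrophages, where it did not reach the minimum for named genes.

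In immune cells fewer UMIs were held and intervals were wide. Mcm3, a replication gene expressed in cycling cells, was higher in T cells of the antibody library, with a ratio of 1.33 (1.11 to 1.61), or 1.36 (1.13 to 1.65) without CD3_T, and lower in the DC cluster, with a ratio of 0.404 (0.243 to 0.662). Arid5a, which stabilises cytokine mRNA, had a ratio of 2.04 (1.37 to 3.14) in MDSC and 1.68 (1.10 to 2.66) in MDSC_1 to MDSC_4, where the median log2 ratio was 0.29. The bound of 1.10 lies below the ratio that this median stands for, so with the median set to 1 the interval would include 1. With clusters weighted alike the Arid5a ratio in MDSC was 1.35. MDSC_5 held 326326 of the 650263 IgG UMIs of MDSC, so ratios of MDSC as a class are not those of neutrophil-like cells. In macrophages Tmem131, a gene for collagen secretion, had a ratio of 1.31 (1.03 to 1.68), and the phosphatase gene Ptpn18 one of 0.857 (0.790 to 0.930). Gsta3 was lower in MDSC (ratio 0.349, 0.234 to 0.517), but in MDSC_1 to MDSC_4 its interval of 0.325 to 1.54 includes 1. In fibroblasts and endothelial cells Sulf1, which trims sulphate from heparan sulphate, had a ratio of 1.35 (1.05 to 1.75).

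After thinning to 1000 UMIs, which left out cells with fewer, a Mcm3 UMI was expected in 9.80% of IgG and 12.4% of antibody T cells (ratio 1.26, 0.776 to 2.09). Without CD3_T the shares were 11.1% and 14.0% (ratio 1.27, 0.768 to 2.15). For tumour cells the shares were 4.58% and 4.71%, for macrophages 7.47% and 7.26%, and for the DC cluster 5.66% and 1.75% (ratio 0.310, 0.0751 to 1.27). MDSC had 2.03% and 0.702%, with 114 of 320 IgG and 282 of 714 antibody cells left out. MDSC_1 to MDSC_4, which as mature neutrophil-like cells should largely lack Mcm3, had 1.03% and 0.169%. The median depths of all MDSC were 1098.5 and 1062 UMIs, against 3067.5 and 2808.5 in T cells. Unthinned shares in T cells were 33.0% and 33.7%, so no difference in cycling T cells was detectable at this depth from shares of cells. Unthinned shares, which also follow depth, had ratios of 1.09 (1.02 to 1.17) in tumour cells and 0.525 (0.278 to 0.978) in the DC cluster.

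The antibody library was also described alone, to show which programs its cell types carried. T cells carried cytotoxic genes and the checkpoint genes Pdcd1, Lag3 and Ctla4. Macrophages carried complement, antigen presentation and the chemokine genes Ccl24 and Cxcl9. MDSC carried Il1b and Cxcl2, together with Cd274, which encodes the checkpoint ligand PD-L1. Tumour cells carried plasma protein genes of hepatocytes. These values say nothing of the antibody's effect, since the same lists were not analysed here in the IgG library. Tumour cells held 62521320 of the 74137900 antibody UMIs used for ratios, so for an immune class the other cells are mostly tumour RNA. A high list thus does not by itself set a class apart from other immune cells, nor mark a state within the class.

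In T cells the cytotoxic list had a median log2 ratio of 6.42 to the other cells, with Ccl5 at 1989 CPM, Nkg7 at 1463 CPM and Ifng at 313 CPM. The checkpoint list stood at 2.01, with Pdcd1 at 222 CPM and Lag3 at 135 CPM. Without CD3_T these 2 lists stood at 6.26 and 2.06, with Ccl5 at 1272 CPM. The naive and memory list stood at 3.35 and the cell cycle list at 1.64. In the CD8_T_1 cluster 45.1% of cells were expected to hold a Mki67 UMI after thinning. The share was 2.76% of the 442 MDSC with at least 1000 UMIs, which include MDSC_5, and 1.78% in MDSC_1 to MDSC_4. Unthinned shares were 91.3%, 5.24% and 2.97%, with median depths of all cells at 5474.5, 1062 and 1047 UMIs. After thinning, a Gzmb UMI was expected in 20.3% of T cells and in 0.0201% of tumour cells. Unthinned, it was found in 38.3% and 0.436%, with median depths of 2808.5 and 20428 UMIs.

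In macrophages the list of alternatively activated genes stood at 5.87, complement at 4.70, MHC class II at 4.25, osteoclast genes at 3.61, chemokines at 3.19 and lysosome and lipid genes at 1.66. C1qa stood at 3117 CPM, Cd74 at 8310 CPM, Ccl24 at 2308 CPM and Acp5 at 432 CPM. MHC class I stood at 1.73 in macrophages and at -1.34 in tumour cells. The DC cluster had 2.59 for the type I interferon list and 2.71 for the proinflammatory list, with Cd74 at 9295 CPM. MDSC_5 held 411216 of the 1231469 MDSC UMIs used for ratios, so MDSC_1 to MDSC_4 are given here. Their list of Siglec receptors and adaptors stood at 4.62, with Tyrobp at 6314 CPM and Cd33 at 334 CPM. The interferon gamma list stood at 2.39 and the dissociation and stress list at 2.43. In fibroblasts and endothelial cells the TGF-beta and matrix list stood at 3.94, with Col3a1 at 9458 CPM. In tumour cells the hepatocyte list stood at 2.38, with Afp at 4038 CPM, and hypoxia and glycolysis at 0.45. Each of these medians lay above the 97.5th percentile of matched random lists, except MHC class I in tumour cells, at the 0th, and hypoxia in tumour cells, at the 85.8th.

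**Figure D4:**
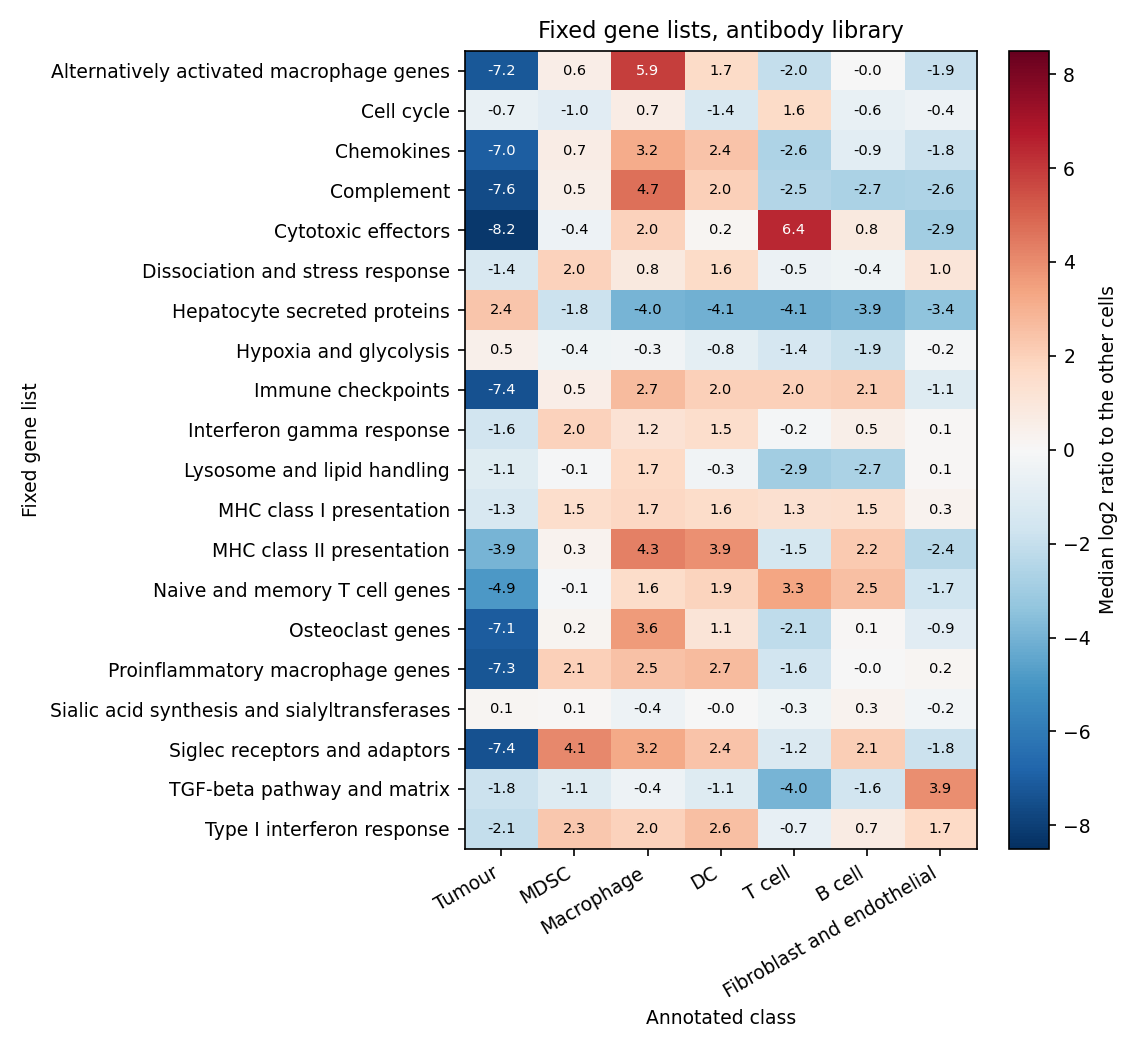
Median log2 ratio of each fixed gene list in a class to all other cells of the antibody library. The cytotoxic list reaches 6.42 in T cells and the list of alternatively activated genes 5.87 in macrophages.

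After thinning, a Cd274 UMI was expected in 34.0% of MDSC, 35.9% of MDSC_1 to MDSC_4 and 65.7% of MDSC_3, against 0.463% of tumour cells. These shares cover the cells with at least 1000 UMIs: 442 of 744 MDSC, 405 of 707 in MDSC_1 to MDSC_4, 106 of 180 MDSC_3 and 3175 of 3213 tumour cells. Median depths of all cells were 1062, 1047, 1059 and 20428 UMIs. Thinned shares were 9.76% in macrophages and 11.2% in the DC cluster, with median depths of 6946.5 and 3796 UMIs. Unthinned shares were 39.9% in MDSC, 41.2% in macrophages, 32.7% in the DC cluster, 6.94% in tumour cells and 24.2% in Tumor_9. By cells holding a UMI, Cd274 is thus not particular to MDSC. MDSC_3 held Isg15 at 6457 CPM and Cxcl10 at 2542 CPM, and MDSC_1 held them at 1520 CPM and 114 CPM.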

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

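The settings of 2000 UMIs, IgG cells of unknown depth kept, clusters weighted alike and clusters left out or put back were chosen after seeing the data. The shares left out MDSC_5, Unknown, Adipocyte, Tumor_4 and Macrophage_4. Of 44 alternatives to 10 ratios of shares, 41 stayed inside the interval of the reported value. The direction stayed the same for 9 of the 10, and the ratio of T cells without CD3_T over immune cells, whose interval includes 1, moved between 0.937 and 1.11. With at least 2000 UMIs the tumour ratio was 0.855, and MDSC_1 to MDSC_4 had ratios of 5.63 over all cells and 3.09 over immune cells. Few of these cells are that deep, 10 in the IgG and 50 in the antibody library. Of 53 alternatives to 14 cluster ratios, 50 stayed inside the interval. MDSC_1 went to 1.83 with at least 1000 UMIs, and MDSC_3 to 4.33 and CD3_T to 2.68 with at least 2000, where MDSC_1 had no IgG cell. The ratios of shares of cells with a Mcm3 UMI stayed inside their intervals in 20 of 20 alternatives, while the shares themselves follow the thinning depth.

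Of 256 alternatives to 47 ratios of shared genes, 175 stayed inside the interval, 69 left it and 12 changed sides of 1. With the median ratio set to 1, all cells gave 0.972 for Arfgef1, 0.958 for Mcm3 and 0.930 for Smap1, and tumour cells gave 0.999 for Tcea1 and 0.994 for Smap1. TMM scaling gave 0.992 for Arfgef1, 0.978 for Mcm3 and 0.948 for Smap1 in all cells, and 0.999 for Smap1 in tumour cells. These changes come from the scaling itself, since each ratio lies close to the median. With clusters weighted alike, all cells gave 0.961 for Ptpn18 and 0.990 for Mcm3, and MDSC gave 0.965 for Neurl3, so the make-up of clusters carried those differences.

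Of 460 alternatives to 140 list medians, 397 stayed inside the counting interval, 58 left it and 5 changed sign. Without MDSC_5, MDSC gave -0.86 for alternatively activated genes, -0.20 for chemokines and -1.35 for complement, so MDSC_5 carried those values. With the median over genes set to 0, the interferon gamma list in B cells went to -0.029 and the lysosome list in MDSC to 0.022, and the cause was not tested. Not run were other clustering resolutions, removal of doublets, marker-based classes for the comparison of libraries, and lists between libraries. For comparing libraries each of these needs genes of the IgG library that were not analysed here. Within the antibody library, other resolutions and removal of doublets were possible but were not run. Leaving out the cell filter changes no antibody cell, and no IgG cell could fail its UMI part. No paired analysis was possible because each group has 1 library, and no replicate could be left out. Depth limits MDSC most, with a median of 526.5 genes per cell in the antibody library.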

Other observations

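All tests of explanations in this part were chosen after the results were seen. Genes for making and attaching sialic acid, the sugar that Siglec receptors bind, had list medians between -0.42 in macrophages and 0.32 in B cells of the antibody library. Their members went both ways, with 8 of 15 higher in tumour cells and 7 of 15 in macrophages. MDSC_1 to MDSC_4 had a median of -0.85. Tumor_9, by genes picked from its own most specific ones, held Cxcl10 at 472 CPM and Iigp1 at 536 CPM, against 6.36 CPM and 32.7 CPM in Tumor_1, which held Vegfa at 424 CPM and Bnip3 at 968 CPM.

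The larger immune share may come from the antibody, from mouse-to-mouse differences or from a different yield of the bead-enriched cells. The ratio of 1.86 cannot be told apart between these, since enrichment and treatment differ between the same libraries. A higher yield of bead-enriched cells alone would not raise the share of fibroblasts and endothelial cells, whose median of immune genes was 0 CPM. Their ratio over all cells was 1.56 (1.21 to 2.03), though for Fibroblast&Endothelial_2 the interval of 0.773 to 1.74 includes 1. Such a yield is thus not the only difference in shares, while its part in the immune share stays open. A yield shared by every immune cell would leave the make-up of immune cells alone, but 7 of 15 immune clusters had a ratio over immune cells whose interval excludes 1. 1 of the 7 is MDSC_5, and with at least 1000 UMIs the count was 5, or 4 of 14 without MDSC_5. Cluster names do not match well in every case, but over immune cells the class ratios of 1.33 for MDSC_1 to MDSC_4 and 0.798 for macrophages also exclude 1. A yield that differs by cell type stays open. The rise of MDSC_1 to MDSC_4 over immune cells was 1.28 (1.08 to 1.53) among cells with at least 1000 UMIs when IgG cells of unknown depth were kept, and 1.40 (1.16 to 1.68) without them, which argues against shallow cells being kept more often as the whole cause.

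In tumour cells Uggt1, Tram1, Dst, Cox5b and Rb1cc1 were higher in the antibody library and Snhg6, Gsta3 and Mrpl15 lower. With tumour clusters weighted alike, 11 of 11 named genes kept over 50% of their log2 ratio, so a shift among clusters is not the whole cause. One scaling factor is not either, since 9 of 11 intervals exclude 1 with the median ratio set to 1, with 6 genes higher and 3 lower. It could account for Tcea1 and Smap1, whose higher ratio then was 0.999. A technical difference in single genes shared by all cells cannot be told apart from a response of tumour cells: the difference to macrophages, adjusted for 11 genes, excluded 0 for 1 gene, Tram1 (log2 difference 0.44, 0.09 to 0.79). The intervals of the other 10 genes include 0. Without adjustment, 3 macrophage intervals exclude the tumour ratio. In macrophages Gsta3 (0.603, 0.393 to 0.926) and Mrpl15 (0.800, 0.660 to 0.972) were lower too, and Cox5b (1.10, 1.03 to 1.18) was higher. Gsta3 did not reach the minimum for named genes in macrophages, which held tumour markers at a median of 574 CPM in the antibody library. How much of that Gsta3 is macrophage RNA is not known, so its lower ratio there does not help to decide. Mrpl15 was also lower in T cells (0.814, 0.670 to 0.992). Tram1 (0.906), Rb1cc1 (0.850), Smap1 (0.921) and Snhg6 (1.03) lay on the other side of 1 in macrophages, with intervals that include 1.

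MDSC_5 held the macrophage genes C1qa, C1qb and Cd68 together with tumour RNA, and the cluster named Unknown held Jchain, Cd3g and tumour RNA. Droplets with 2 cells are a candidate explanation: 35.1% of MDSC_5 and 44.2% of Unknown cells in the antibody library were predicted doublets, against 1.22% of all cells. Free tumour RNA alone would be alike in the other MDSC, but the median of tumour markers in MDSC_5 was 5.91 times the highest of MDSC_1 to MDSC_4, or 6187 against 1047 CPM. The design gives no biological explanation to test here.

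Assigning each antibody cell to the class with the highest marker expression gave the annotated class for 87.2% of MDSC, 82.9% of T cells, 60.2% of macrophages and 36.5% of the DC cluster. Of the 208 cells of the DC cluster 86 went to MDSC. That class here pooled neutrophil and monocyte markers, so these cells need not be neutrophil-like. The assignment gave 59.7% for tumour cells, of which 492 went to DC and 467 to fibroblasts and endothelial cells, and 65.9% over all named classes. The cluster named Adipocyte held 32 IgG cells and 2 antibody cells, with median depths of 874 and 10945.5 UMIs. With at least 1000 UMIs it held 10 and 2, and the interval of the ratio (0.0229 to 1.01) includes 1. Across shared genes the IgG cells were closest to Tumor_5, with their own name at rank 16, so no difference is read from this name.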
